A study of Drosophila melanogaster with 3 samples.

How the data were processed

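The study used circular chromosome conformation capture (4C), in which chromatin is cross-linked, cut with the enzyme DpnII and ligated so that DNA lying close to a chosen bait fragment in the nucleus becomes joined to it. The joined DNA is then amplified outward from the bait by inverse PCR. Per the labels, S2-DRSC cells, a line of embryonic Drosophila melanogaster cells, served as the material for 3 baits. BaitA lies on chromosome arm 3R at 91997 to 92920, BaitB on 2L at 8485115 to 8485894 and BaitC on 3R at 384440 to 385252. Each bait had 1 tiling array with 2 channels: the 4C products were in Cy5, and DpnII-cut genomic DNA that had not been ligated was in Cy3, per the labels. The unligated DNA is the background of each array. Labelling was done at a NimbleGen facility, per the labels' protocols. With 1 array per bait, no difference between baits has a replicate check, no test between arrays was run and no p-value is given. Per the file headers, BaitB and then BaitA were hybridised to the same slide, and BaitC was the third hybridisation of another slide, whose earlier uses are not given in the sources used here.

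The deposited values per probe are log2 ratios of the 2 channels. The log base and the direction are not written in the table. The mean plus 6 SD of these values on each arm equals the reference height of the deposited peak lists, and the values are raised around each array's own bait, so that the 4C channel is the numerator. The values do not settle the base, and base 2, the convention of the peak software, was assumed. The step that centred the ratios before deposit is not given in the sources used here: the deposited medians were -0.16 for BaitA, -0.14 for BaitB and -0.02 for BaitC. Each array was centred on the median of all its probes, which moved the values by those amounts. Centring on the probes of the arms without the bait moved the BaitB values by a further 0.26, the BaitA values by -0.05 and the BaitC values by -0.02. Each array held 2157868 probes at a median step of 55 bp, and all value columns belonged to a sample. Because PCR products saturate and are compared with genomic DNA, a ratio is not a contact frequency.

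Per the file headers, peaks were called with NimbleScan on each array separately, with shuffled values as the estimate of false peaks. The peak score is on the log2 ratio scale: it is the highest threshold at which the peak was called, expressed as a percentage of the arm's mean plus 6 SD, so a given percent of that reference is a different height on each arm. The false discovery rate (FDR) deposited with each peak plays the part of a q-value and can exceed 1 for the lowest peaks. The scores and FDR values are the authors', and were used only to filter and rank peaks within a list. The authors' deposited peak-to-feature tables pair the peaks of FDR at most 0.2 with transcripts and transcription start sites within 5 kb. They give transcript spans and not exons, so positions are described as inside or outside a transcribed span. A p-value of any other kind was not among the deposited values used.

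Coordinates are those of the deposited files. The build is not named there, and the arm lengths in the file headers, such as 23011544 bp for 2L and 27905053 bp for 3R, are those of Drosophila Release 5. The gene table supplied with the data is of Release 6 and was used for names alone. By RefSeq accession without version, 16169 of the 17767 accessions in the peak-to-feature tables matched it. An accession without a match took the symbol shared by the other accessions of the same name, or kept its name in the file. This left 12209 genes, of which 12206 had at least 5 probes within 1 kb of a start site. Only genes paired with a peak of FDR at most 0.2 in some bait are in this set.

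Probes were averaged in 10 kb bins holding at least 20 probes. Peaks of FDR at most 0.05 were counted per arm and per Mb covered by bins. For the bait arm against the other major arms and chromosome 4, peaks within 20 kb of the bait were left out, and the ratio of densities has an exact 95% binomial interval that covers counting error only. Reciprocal signal was the mean within 5 kb of another bait. It was set against windows of that size on the same arm, at 50 to 200% of the distance where both baits share an arm. Profiles were compared by Pearson's r over bins, with 200 kb around every bait left out and 1000 circular shifts of a profile along each arm as the comparison. The SD of r came from resampled blocks of 1 Mb. Peak sets were compared by overlaps of at least 1 bp, with no zone around the baits left out and again with 1000 circular shifts. Bins, peaks and genes of 1 array are not independent replicates, and percentiles describe these arrays.

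The 10 gene lists, the settings, the alternatives and the rule for named genes were fixed before the data were examined. The lists were Hox genes, Polycomb targets outside the Hox clusters, ribosomal protein genes, ecdysone response genes, heat shock genes, genes of insulator and architectural proteins, hemocyte markers, neuron markers, muscle markers and glycolysis genes. The value of a list was the median over its members of the mean ratio within 1 kb of the gene starts, with members within 200 kb of the bait left out. Its percentile was taken among 10000 random lists of the same size matched on arm but not on distance from the bait. Of the names on the fixed lists, some of them older names for the same gene, the set held 11 of 23 for heat shock, 14 of 21 for architectural proteins and 13 of 17 for neuron markers, so these lists were measured only in part. Named genes were those whose span overlaps the bait, up to 8 genes nearest to the bait beyond 20 kb that are paired with a peak of FDR at most 0.05, the 8 genes beyond 100 kb on the bait arm and the 8 on other arms with the highest peaks, and the 8 genes with peaks in all 3 baits whose lowest height was highest. For each list up to 4 members with the highest values were eligible, and up to 2 with the lowest where the list was lower. The alternatives changed the FDR limit, merging of peaks, the zone left out, bin size, centring, the summary of probes, window size, the kind of correlation, the overlap rule and the matching of random lists. Alternatives that changed the FDR limit of a list's share of members with a peak had no value to change, since lists were measured by ratios. One peak height for all arms, circular shifts for the shared genes, and medians or uncentred values for named peaks were added after the data were seen.

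Parts of the steps were tested on simulated data. With 10% of 4000 simulated peaks planted as shared, the overlap beyond shifts was 9.83%, and with none planted it was 0.0837%. These peaks were placed at random on the major arms, without the clustering of real peaks. A planted correlation of 0.5 over 13000 independent bins was recovered as 0.500, which checks r alone and not the shifts or the resampled blocks. Of 100 random lists of 20 genes drawn from 12082 genes of the BaitA array, 1 lay above the central range of random lists with no shift planted, 27 did with 0.5 added on the log2 scale, 58 with 1 added and 100 with 2 added. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.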

Results

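Contacts of 3 insulator binding sites of the Drosophila genome were mapped in S2-DRSC cells by 4C on tiling arrays. Insulators are DNA elements whose bound proteins take part in chromosome folding, and the study asked which sites on the same and on other chromosomes lie near each of them. BaitA and BaitC sit 292 kb apart near the end of 3R that borders the centromere, and BaitB sits on 2L. There was 1 array for each bait, so the spreads given below are over probes or bins within an array and no value has a replicate error. The number of arrays limits the precision. All ratios are log2 of 4C product over unligated DNA, centred on the array median. The SD over all probes was 2.45 in the BaitA array, 2.50 in the BaitB array and 1.50 in the BaitC array.

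Each array was raised at and around its own bait. The 17 probes inside BaitA averaged 8.34 ± 1.05 (SD over probes) in the BaitA array, the 14 probes inside BaitB averaged 8.57 ± 0.58 in the BaitB array, and the 15 probes inside BaitC averaged 7.53 ± 0.58 in the BaitC array. BaitA overlaps the transcribed span of CG1092 (3R, 92675 to 93935), and the highest peak paired with that gene, at 92350 to 92784, had a mean of 8.74 over 8 probes. BaitB lies inside the span of d (2L, 8482483 to 8488215), the dachs gene, which encodes an unconventional myosin of the Fat pathway. The highest peak paired with d, 2202 bp outside its span at 8479579 to 8480281, averaged 9.25 over 13 probes. No span in the peak-to-feature tables overlaps BaitC.

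The ratio declined with distance over the first 5 Mb of the bait arm in all 3 arrays. BaitA and BaitC lie near the centromere, so on 3R distance from the bait is also distance from the centromere. The 1 Mb of 2R next to the centromere, without a bait, averaged 2.02 ± 0.58 (SD over bins) in the BaitA array and 0.42 ± 0.36 in the BaitC array. That of 3R was at 0.02 ± 0.96 in the BaitB array. Values of this size further along 3R thus cannot be read as the reach of contacts alone. In the BaitA array the 4 bins up to 20 kb away averaged 8.04 ± 0.09 (SD over bins), those from 20 to 100 kb averaged 6.81 ± 0.73, those from 200 to 500 kb averaged 3.28 ± 0.69 and those from 1 to 2 Mb averaged 1.08 ± 1.08. Beyond 10 Mb the mean was -0.34 ± 0.90. In the BaitB array the same classes gave 8.29 ± 0.49, 6.85 ± 1.39, 4.63 ± 0.69 and 2.09 ± 0.98, and the mean then rose from 0.46 ± 0.98 between 5 and 10 Mb to 0.67 ± 0.99 beyond 10 Mb. The BaitA and BaitC arrays also rose over these bins of 2L, from 0.25 to 0.79 and from -0.16 to 0.02. In the BaitC array they gave 5.32 ± 0.89, 4.51 ± 0.68, 1.28 ± 0.71 and 0.17 ± 0.55, with -0.09 ± 0.51 beyond 10 Mb. From 1 to 2 Mb, 7 of 100 bins exceeded the 99th percentile of bins on other major arms for BaitA, 112 of 200 for BaitB and 5 of 100 for BaitC. Around BaitB the other arrays stayed between -0.15 and 0.91 in the classes up to 500 kb. On 3R, BaitA and BaitC each lie within the raised stretch around the other. The BaitA array thus averaged 3.25 up to 20 kb from BaitC, and the BaitC array 1.68 up to 20 kb from BaitA.

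**Figure D1:**
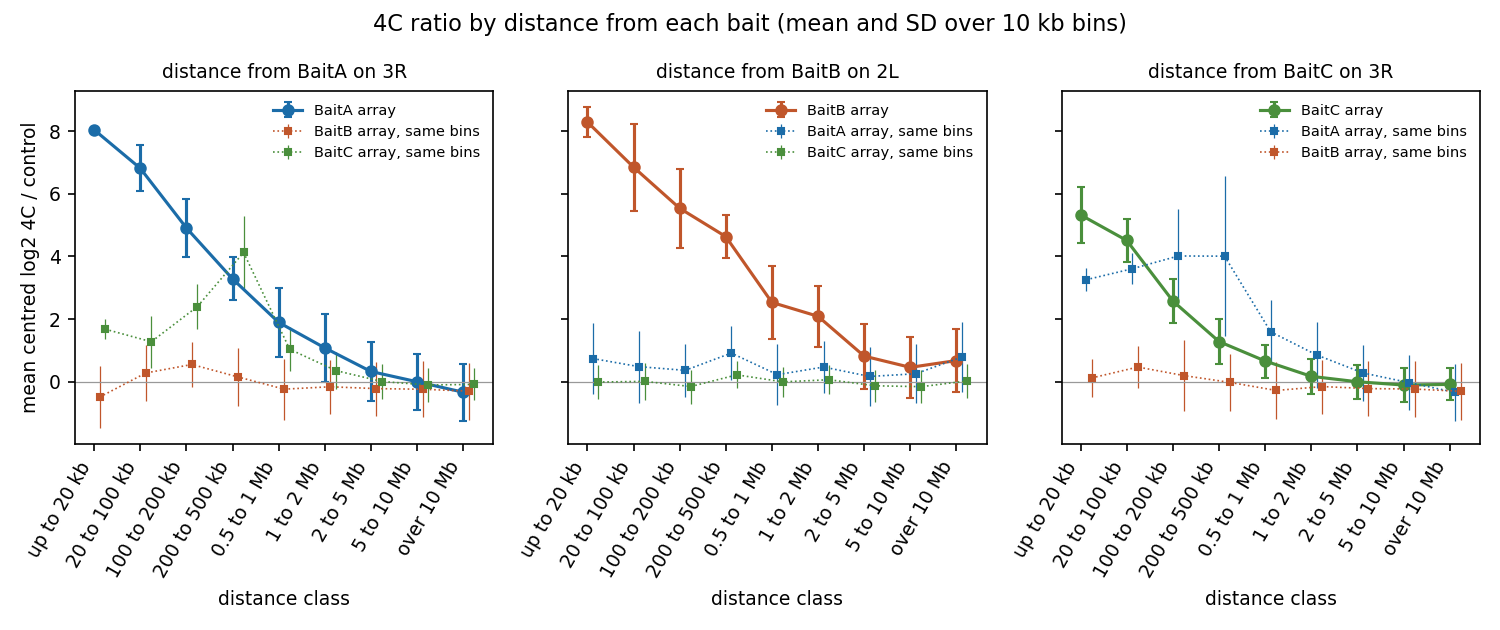
Mean centred log2 ratio of 4C over control (vertical axis) by class of distance from BaitA, BaitB and BaitC (horizontal axis), as means with SD over 10 kb bins. Filled circles are the bait's own array and small squares the other arrays over the same bins. The own array falls from 8.04, 8.29 and 5.32 up to 20 kb to 1.89, 2.53 and 0.66 between 0.5 and 1 Mb.

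The genes nearest to each bait beyond 20 kb that carried a peak lay within the raised stretch around that bait. Around BaitA these were CG14638, CG14642, Nepl11, Gel, abs, CG14641, DhpD and aux. Gel encodes gelsolin, an actin-severing protein, and the peak over it (3R, 62866 to 66843) averaged 8.24 ± 0.53 over 73 probes, while the BaitB array gave 0.31 and the BaitC array 2.33 there. The peak at Nepl11 (3R, 118095 to 120846) averaged 8.07, and the one at aux (3R, 46271 to 47125), which encodes the clathrin-uncoating factor auxilin, averaged 7.58. Around BaitB they were CG13096, CG13097, PIG-U, mRpL51, Uba4, Sgp, Agpat2 and Aasdh. The peak at mRpL51 (2L, 8515609 to 8516815), a mitochondrial ribosomal protein gene, averaged 8.50 ± 0.41 over 23 probes against 0.16 in the BaitA array. Around BaitC they were CG14652, CG41467, CG31526, CG12587, CG9783, 5-HT2A, Fip1 and sac. The peak in 5-HT2A (3R, 450130 to 451345), which encodes a serotonin receptor, averaged 5.43 ± 0.48 over 23 probes. The peak at sac and Fip1 (3R, 307563 to 308217) averaged 5.82 in the BaitC array and 6.15 in the BaitA array.

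Beyond 100 kb on the bait arm, the highest BaitA peak lay inside ohgt (3R, 5875389 to 5875973), 5782.1 kb from the bait. It averaged 7.13 ± 0.30 over 11 probes, against -1.66 in the BaitB array and 2.34 in the BaitC array, and was also paired with CG12811, Npc2e and CG11722. The other BaitA genes of this kind were Sfxn1-3, CG14646, CG9855 and CG34112, 112 to 129 kb from the bait, with means from 6.75 to 6.84. For BaitB all 8 genes lay between 101.1 and 200.4 kb from the bait: CG9289, PrBP, Trs23, CG9287, Dad1, CG13392, Glt and Wdr82. The peak shared by the first 4 of them (2L, 8683966 to 8684435) averaged 8.04 ± 0.32 over 9 probes. For BaitC the highest were at cas (3R, 1543096 to 1543685), a zinc finger gene of neuroblasts, with 6.74 ± 0.60, at CG33335 (3R, 17991657 to 17991986) with 7.28 ± 0.70, at a peak inside CG7903 that was paired also with Sas-6, Acph-1 and CG11504 (3R, 25820247 to 25820681) with 6.71 ± 0.69, and at CG2224 and CDase (3R, 26284843 to 26285382) with 5.61 ± 0.95. The CG7903 interval was at -2.01 in the BaitB array and about as low in the BaitA array. The CG2224 and CDase interval was at 4.84 in the BaitA array and 2.45 in the BaitB array. The cas and CG33335 intervals were at 3.97 and 3.63 in the BaitB array, and at -0.67 and -2.02 in the BaitA array.

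On other arms the highest peaks were short and lower in the other arrays, which follows in part from picking them by height. For BaitA they were paired with CG34124 and CG34125, with Piezo and fos28F, with CG10383, CG10338 and msl-1, and with Dscam1. The peak in Piezo (2L, 8176315 to 8176588), a mechanically gated channel gene, averaged 7.23 ± 0.40 over 6 probes. It lies between 200 and 500 kb from BaitB, whose product was hybridised to the same slide before, and its interval averaged 2.60 ± 2.50 in the BaitB array. The one inside CG10383 (2L, 18692806 to 18693295) averaged 7.05 ± 0.37. It lies 2846 bp from CG10338 and 4381 bp from msl-1, a gene of the dosage compensation complex. The Dscam1 peak (2R, 3236321 to 3236637) averaged 7.20 ± 0.69 in the BaitA array and 4.14 ± 0.42 in the BaitC array. For BaitB they were paired with insc, with kug, with Adk1 and eIF3d2, with CG14488, OstDelta and CG18635, and with spdi. The peak inside Adk1 lies 3836 bp from eIF3d2. The peak in insc (2R, 16711037 to 16711306), a gene of asymmetric neuroblast division, averaged 6.95 ± 0.94, and that in kug (3L, 20003336 to 20003629), a Fat-like cadherin gene, averaged 6.84 ± 0.41. In the BaitA array the insc and Adk1 intervals were at 3.37 and 4.15, and the kug interval at -1.50. For BaitC they were paired with mtt, with CG15894, with Six4 and tzn, with CG8172, with CG17378, with CG13110 and with CG14915. The peak shared by Six4 and tzn lies 1596 bp from Six4 and 4702 bp from tzn. The peak in mtt (2R, 4367940 to 4368394) averaged 7.34 ± 0.57 over 9 probes, against -2.44 in the BaitA array and -2.34 in the BaitB array. That in CG15894 (X, 6217598 to 6218072) averaged 7.28 ± 0.32, against -1.48 and -2.44. Other BaitC intervals were raised elsewhere too. That of CG14915 was at 4.06 in the BaitA array and 3.54 in the BaitB array, and that of CG13110 at -1.61 and 4.04. The flanks 1 to 10 kb from the peak averaged 0.22 at mtt and -0.09 at CG15894 in the BaitC array. They averaged 2.04 at Piezo, 0.56 at CG10383, 0.49 at Dscam1 and 0.23 at CG34124 in the BaitA array. In the BaitB array they averaged -0.23 at insc and -0.13 at kug.

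Peaks of FDR at most 0.05 numbered 3854 for BaitA, 4434 for BaitB and 3588 for BaitC, and 500, 912 and 794 of them lay on the bait arm. On X there were 876, 1088 and 827. Within 200 kb of the bait there were 150, 201 and 214. With 20 kb around the bait left out, the bait arm held 17.3 peaks per Mb for BaitA against 29.8 on the other arms, a ratio of 0.581 (exact 95% binomial interval 0.526 to 0.640). For BaitB the densities were 38.8 and 31.3, a ratio of 1.24 (1.15 to 1.34), and for BaitC 27.5 and 27.1, a ratio of 1.01 (0.933 to 1.10). The BaitA direction depended on the setting. It was kept at 0.602 with no zone left out, 0.426 with 200 kb around the bait left out and 0.938 for all deposited peaks. With one peak height for all arms the ratio was 1.07 (0.970 to 1.17, an interval that spans 1), at FDR at most 0.01 it was 1.60 (1.24 to 2.06), and for 10 kb bins among the top 1% it was 3.65 (2.51 to 5.31). The lowest height that passed the FDR limit in the BaitA array was 4.86 on 3R and 4.07 on X. On 2L, 2R and 3L it was 4.64 to 4.83, close to that of the bait arm. In the BaitB array it was 5.24 on 2L, 4.45 to 4.65 on 2R, 3L and 3R, and 4.04 on X. In the BaitC array it was 3.08 on 3R, 2.91 to 2.94 on 2L, 2R and 3L, and 2.86 on X. For BaitB the ratio was 1.02 (0.934 to 1.10) with 200 kb around the bait left out and 9.04 with one peak height, and all 120 of the top bins lay on 2L. For BaitC the ratio was 1.64 with one peak height and 5.31 for top bins, and it was 0.779 with 200 kb around the bait left out.

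Signal outside the bait arm differed between chromosomes. In the BaitA array the mean over 10 kb bins was 0.37 ± 0.99 (SD over bins) on 2L, 0.39 ± 1.02 on 2R, 0.13 ± 0.99 on 3L, -0.47 ± 0.81 on X and 1.03 ± 0.85 on chromosome 4. In the BaitB array it was 0.28 ± 0.96 on 2R, -0.03 ± 0.94 on 3L, -0.27 ± 0.90 on 3R, -0.49 ± 0.82 on X and 0.49 ± 0.69 on chromosome 4. In the BaitC array it was -0.08 ± 0.52 on 2L, -0.06 ± 0.52 on 2R, -0.05 ± 0.54 on 3L, 0.24 ± 0.49 on X and 0.55 ± 0.39 on chromosome 4. The heterochromatic scaffolds of chromosomes 2 and 3 together averaged 1.88 ± 0.83 in the BaitA array, 1.14 ± 0.67 in the BaitB array and 0.48 ± 0.41 in the BaitC array. The scaffold of 3R, the arm of BaitA and BaitC, was at 2.25 ± 1.06, 0.94 ± 0.62 and 0.64 ± 0.37 in the BaitA, BaitB and BaitC arrays, and that of 2L, the arm of BaitB, at 2.28 ± 0.60, 1.69 ± 0.69 and 0.43 ± 0.34. The X differed from the autosomal arms without the bait by -0.76, -0.46 and 0.31 in the BaitA, BaitB and BaitC arrays, and the error of these differences between arrays was not measured.

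**Figure D2:**
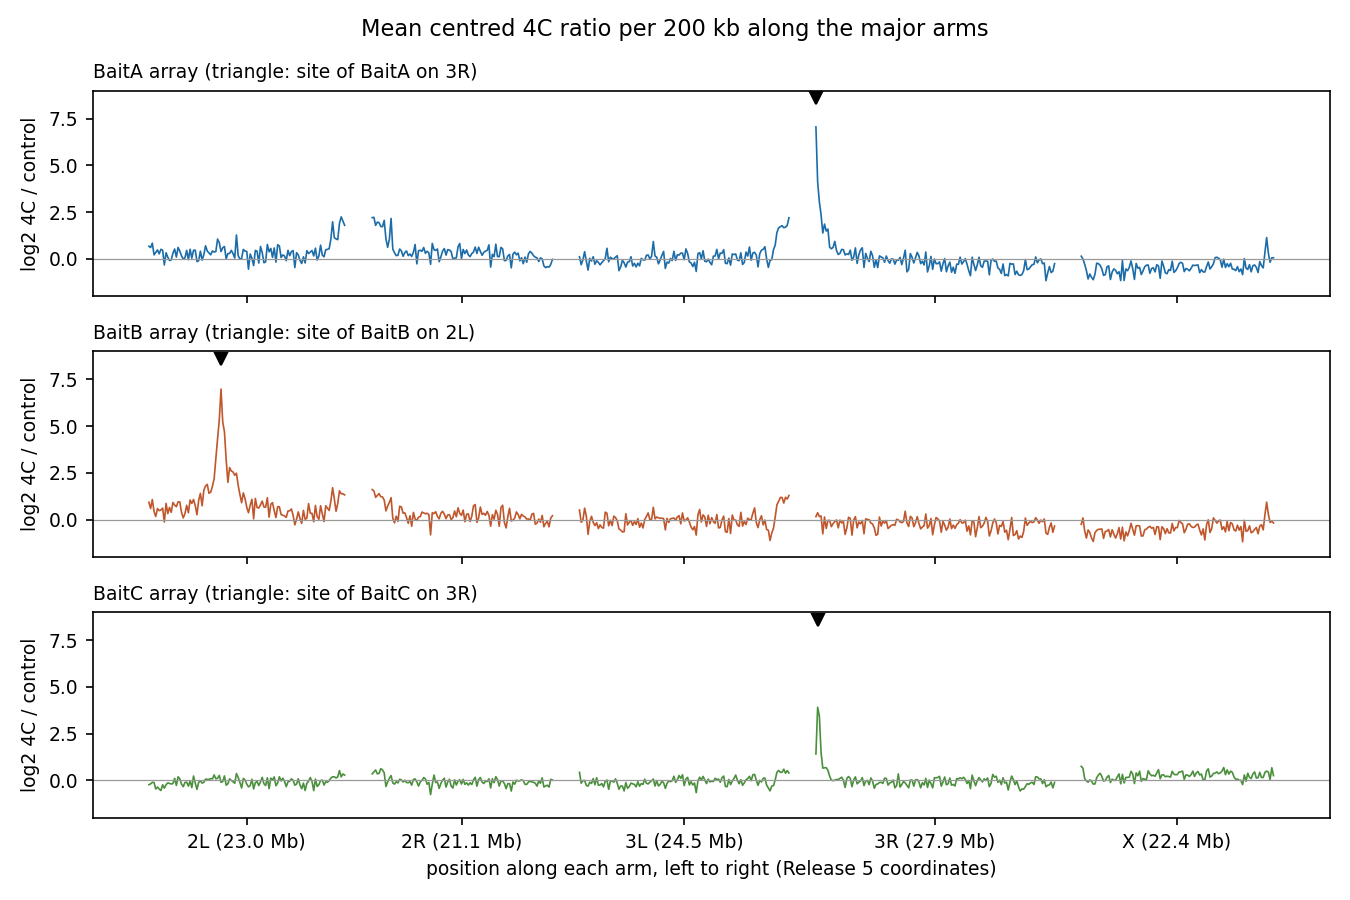
Centred log2 ratio of 4C over control (vertical axis), averaged per 200 kb, along the major arms 2L, 2R, 3L, 3R and X (horizontal axis, positions left to right), with a row per array and a triangle at its bait. Each profile is highest around its own bait, and the X lies at -0.47 in the BaitA array, -0.49 in the BaitB array and 0.24 in the BaitC array.

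Whether the baits contact each other was read from the signal of each array within 5 kb of the other baits. The BaitA array averaged 3.03 ± 1.28 (SD over 193 probes) at BaitC, at the 36.1st percentile of windows on 3R at a comparable distance from BaitA. The BaitC array averaged 2.02 ± 1.43 over 83 probes at BaitA, at the 80.0th percentile of its comparable windows. Between chromosomes, the BaitA array averaged 1.48 at BaitB (88.2nd percentile of 2L windows) and the BaitC array 0.55 (89.6th). The BaitB array averaged 0.66 at BaitA (85.2nd percentile of 3R windows) and -0.08 at BaitC (56.9th). None of these 6 values was outside the central 95% of its windows. The values between chromosomes depended on the window: within 1 kb the BaitA array gave -0.027 at BaitB, the BaitB array 1.59 at BaitA (90.0th percentile) and the BaitC array 1.11 at BaitB (93.9th), and within 20 kb the BaitB array gave -0.65 at BaitA and the BaitC array -0.051 at BaitB.

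The profiles of the 3 arrays resembled each other away from the baits. Over 13456 bins Pearson's r was 0.525 ± 0.026 (SD over resampled blocks) between BaitA and BaitB, 0.503 ± 0.023 between BaitA and BaitC and 0.410 ± 0.028 between BaitB and BaitC. After circular shifts the mean r was 0.259, 0.172 and 0.108, and no shift of the 1000 reached the observed value. These bins include the heterochromatic and unplaced scaffolds, which were raised in all 3 arrays. Within single major arms r ran from 0.329 on 3R to 0.448 on 2R for BaitA and BaitB, from 0.459 on 2L to 0.508 on 3L for BaitA and BaitC, and from 0.380 on 3R to 0.463 on 3L for BaitB and BaitC. Of the BaitA peaks, 8.74% overlapped a BaitB peak (337 of 3854, exact 95% binomial interval 7.87 to 9.68%) and 2.77% did after shifts. With BaitC peaks 7.32% overlapped (6.51 to 8.19%) against 2.20%, and 7.69% of the BaitC peaks overlapped a BaitB peak (6.84 to 8.61%) against 2.83%. The peaks include those on the heterochromatic and unplaced scaffolds, 617 for BaitA, 492 for BaitB and 306 for BaitC. Shifts ran over the full length of each scaffold, including stretches without probes. Overlap on the major arms alone was not computed. Peaks near the baits were not left out of these overlaps. BaitA and BaitC lie 292 kb apart, with 150 BaitA peaks and 214 BaitC peaks within 200 kb of their baits. The stretch of 3R raised in both arrays can thus add to their overlap, by an amount that was not measured, and shifts move it apart. Whether the arrays share their control DNA is not given in the sources used here, and shifts do not remove similarity from that source. BaitA and BaitB were hybridised in turn to the same slide and BaitC to a reused slide, per the file headers, which differs between the pairs of arrays compared.

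Of 12207 gene names in the peak-to-feature tables, 3870 were paired with a BaitA peak, 4603 with a BaitB peak and 3801 with a BaitC peak of FDR at most 0.05. Peaks of all 3 baits were paired with 672 genes, where the product of the shares gives 454, and 2621 genes had peaks of exactly 2 baits. The set holds only genes paired with a mapped peak of some bait, so the product is a rough comparison. The genes with the highest peaks in all 3 baits were sls, Dscam1, CG40323, Prp8, exp, CG18190, CngB and Jheh1. The peaks of the 3 baits lay at different places in or near these genes, and the span given for CG40323 runs from 2014801 to 9415013 of the unplaced scaffold U, so it does not stand for a single site. In sls, the titin-like muscle gene (3L, 2040381 to 2114297), the BaitA peak at 2056013 to 2056349 averaged 5.98 ± 0.36, the BaitB peak at 2090783 to 2091102 averaged 5.77 ± 0.48, and the BaitC peak at 2085118 to 2085433 averaged 5.81 ± 0.26, at which the BaitA array was at -1.82 and the BaitB array at -2.54. In Prp8 (2R, 8041881 to 8050198), a core splicing factor gene, the BaitB peak averaged 5.26 ± 0.46 and the BaitC peak 5.45 ± 0.72, while the BaitA peak 1039 bp outside the span averaged 5.61 ± 0.45. Jheh1, which encodes a juvenile hormone epoxide hydrolase, and its neighbour CG18190 were paired with the same peaks on 2R.

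The gene lists asked whether functional groups of genes stood closer to a bait than other genes on their arms. Of the 30 medians of 10 lists in 3 arrays, 2 lay outside the central 95% of random lists, where chance gives 1.5. Both were in the BaitC array. The 13 neuron markers in the set, of 17 names fixed and genes of a cell type other than S2 cells, had a median of -0.45, at the 0.39th percentile, with 3 members above the median of their arm. Among them nSyb (-1.38) and Gad1 (-1.04), genes of synaptic vesicle fusion and GABA synthesis, were lowest, and the calcium channel gene cac (2.56) was highest. The 18 muscle markers had a median of 0.72, at the 98.2nd percentile, with 14 above the median of their arm, led by sls (1.72), TpnC47D (1.66), wupA (1.36) and up (1.19). With probes within 5 kb these lists stood at the 2.72nd and the 76.2nd percentile, inside the range. In the other arrays the neuron markers stood at the 60.5th (BaitA) and 65.1st (BaitB) percentile and the muscle markers at the 88.4th and 90.9th.

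The Hox genes, the clustered regulators of body segment identity on 3R, had a median of 1.23 over 8 members in the BaitA array (91.1st percentile), with lab at 3.04, Antp at 2.30 and pb at 2.29 but Dfd at -2.09 and abd-A at -0.59, and of -0.26 in the BaitB array (26.2nd) and 0.07 in the BaitC array (27.3rd). The 34 Polycomb targets outside those clusters stood at the 14.3rd, 55.2nd and 45.9th percentile in the BaitA, BaitB and BaitC arrays. Doc2 was highest in the BaitA array (3.13), salr, on the bait arm, in the BaitB array (3.20) and slp1 in the BaitC array (1.36). In the BaitA array 8 of the 34 lay in the lowest 10% of genes on their arm, where 3.4 are expected, with hh at -2.77 and ph-p at -2.29, and 1 lay in the highest 10%. In the BaitB and BaitC arrays 4 lay in the lowest 10%. The BaitA count was picked from such counts for every list and array. The ribosomal protein genes had medians of 0.80, 0.58 and 0.22, at the 97.4th, 79.5th and 36.3rd percentile, with RpL7 at 3.58 in the BaitA array. RpL36A was at 4.50 in the BaitB array and lies on 2L between 200 and 500 kb from BaitB, where bins averaged 4.63. Within 5 kb this list was at the 99.9th percentile in the BaitB array and at the 74.5th in the BaitA array. Against random lists from any arm it stood at the 97.6th percentile in the BaitA array, just outside the range.

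The genes of insulator and architectural proteins, the factors that bind such sites, stood at the 26.7th, 73.3rd and 25.6th percentile over the 14 members in the set, of 21 names fixed. CTCF was at 3.20 in the BaitB array and -0.47 in the BaitC array, and su(Hw) at 1.36 in the BaitC array. Hemocyte markers, the lineage S2 cells resemble, stood at the 89.8th, 25.0th and 34.5th percentile over 13 members, with gcm at 2.83 in the BaitA array and NimC1, on the bait arm, at 3.54 in the BaitB array. Of 23 names fixed for heat shock genes, the 11 genes in the set stood at the 66.8th, 92.2nd and 69.4th percentile, with Hsp22 at 2.62 in the BaitA array and Hsp68 at 1.83 in the BaitC array. The 20 ecdysone response genes stood at the 37.4th, 35.6th and 16.7th percentile, and within 5 kb they stood at the 1.30th in the BaitC array, outside the range of random lists. The 11 glycolysis genes stood at the 66.9th, 38.0th and 45.9th percentile, with Pfk at 2.70 in the BaitA array and 1.79 in the BaitC array.

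**Figure D3:**
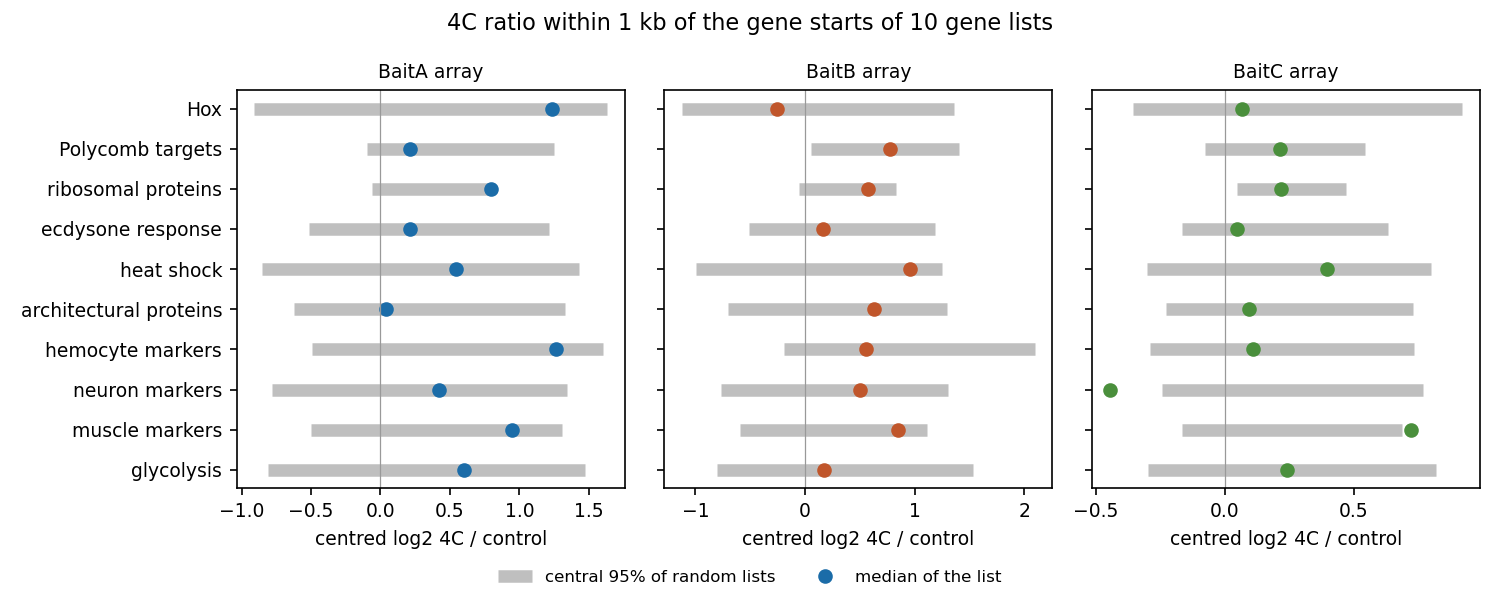
Median centred log2 ratio of 4C over control within 1 kb of gene starts (horizontal axis) for 10 gene lists (rows) in each array. Circles are list medians and grey bars the central 95% of 10000 random lists matched on arm; the neuron markers (-0.45) and muscle markers (0.72) of the BaitC array lie outside their bars.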

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

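The tests on the centromere-proximal ends, the test on the bins with the least spread and the test that compares flanks between arrays were chosen after the results had been seen.

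The X chromosome stood below the autosomal arms without the bait by -0.76 on the log2 scale in the BaitA array and by -0.46 in the BaitB array, and above them by 0.31 in the BaitC array. The direction thus differed between baits, and with 1 array each the difference was not tested.

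Signal also appeared on scaffolds whose levels are not given above, although the profile correlations and peak overlaps include them. On the Y scaffold (YHET) the mean ratio was 2.15 in the BaitA array, 1.80 in the BaitB array and 2.11 in the BaitC array. On the unplaced scaffolds (U) it was 1.70, 1.37 and 1.02, and on the X scaffold (XHET) 0.76, 0.22 and 0.57.

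The Y scaffold was raised to a similar level in all 3 arrays with little spread between probes. A candidate explanation is DNA that these cells lack, so that both channels read background and the ratio is a constant of the array. The bins of the major arms whose probes spread least in all 3 arrays were 3 neighbouring bins on 3L at 20001 to 50000, around mthl8. Of these, 100% lay within 2 SD of the Y level in every array, as that explanation needs. The pattern had been seen before this test was chosen and rests on a single region, so the test decides nothing. The bins were at 2.43 to 2.47, 2.06 to 2.15 and 2.70 to 2.82 in the BaitA, BaitB and BaitC arrays. The Y means there were lower, at 2.15, 1.80 and 2.11. For contacts of all 3 baits with these regions, the probe SD on the Y scaffold was set against that of bins at the same ratio. It was 0.396 and 0.303 of that value in the BaitA and BaitB arrays, and 0.787 ± 0.066 (SD over resamples) in the BaitC array. All were under 0.8, the bound set beforehand as going against contacts. The BaitC value was under it by less than its SD, so contacts could not be excluded. Neither explanation was settled, so a raised ratio there should not be taken as contact.

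The 1 Mb next to the centromere on 2R and 3L, arms without any of the baits, exceeded the parts over 5 Mb away by 1.83 ± 0.07 (block SE within the array) in the BaitA array, 1.24 ± 0.06 in the BaitB array and 0.55 ± 0.03 in the BaitC array. The excess was smaller on X, also without a bait, at 0.76, 0.70 and 0.15. On 3R it was 0.31 in the BaitB array. The excess and its order between baits thus do not hold for every arm. Carry-over from BaitB is argued against as the source of the BaitA excess. Per the file headers, BaitB was hybridised to the same slide before BaitA. Within 100 kb of the BaitB site, the BaitA excess was lower than its centromere-proximal excess of 2L, 2R and 3L by -1.45 ± 0.27. The BaitA array averaged 0.91 ± 0.87 (SD over bins) between 200 and 500 kb from BaitB, outside the window of this test. Probes that read background in both channels stay open. That explanation needs the same share of the distance to the Y level in every array. The excess on 2R and 3L was 88.6%, 70.3% and 24.9% of that distance. The range of 63.7 ± 4.7 percentage points (block SE) goes against it within the arrays but has no error between arrays. The SD over probes was 1.79, 1.84 and 1.24 where a mixture with such probes would give 1.46, 1.80 and 1.73. Closeness of BaitA and BaitC to the 3R centromere needs a higher excess in both than in BaitB. The lower of their excesses minus that of BaitB, in SD over bins, was -0.30 ± 0.10 (block SE) on 2R and 3L. That is the opposite direction, but it has no error between arrays, so this explanation stays open as well. With 2L included, whose reference holds the raised stretch around BaitB, the value was 0.193 ± 0.099. With 1 array per bait these explanations cannot be told apart.

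The highest BaitC peaks on other arms, such as those in mtt and CG15894, stood alone between flanks near the array median. Flanks of the BaitB peaks in insc and kug were near the median as well, at -0.23 and -0.13 in the BaitB array. Probe behaviour shared by the arrays stays open. At the 1152 further BaitC peaks on other major arms with FDR at most 0.01, the other arrays were compared with shifted positions. Their mean excess was 12.8% of the BaitC excess. These peaks were picked for their height in the BaitC array, so a low share elsewhere follows in part from the choice and decides nothing. The BaitA and BaitB arrays were still raised there by 0.42 and 0.52. Contact with a wider region around each peak stays open: the flank excess in the BaitC array minus the mean of the other arrays was -0.0093 ± 0.025 (SD over shifts) on the log2 scale but 0.0320 ± 0.0128 in SD over probes, so the answer depends on the scale. Single fragments taken up in the amplification cannot be told apart from short contacts. The flank excess of 0.14 ± 0.01 exceeded the bound set beforehand for single fragments, but that bound overlooked effects of position: the BaitA and BaitB arrays had an excess of 0.12 and 0.17 at these flanks.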

How the results depend on the processing

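With 1 array per bait, the settings below show the effect of processing and not of replication; the cause was not tested where a value moved. One peak height for all arms, circular shifts for shared genes, and medians or values as deposited for named peaks were chosen after the data were seen. The decline with distance kept its value within the SD over bins in 133 of 135 alternatives; the bins up to 20 kb of BaitA gave 7.85 with 50 kb bins and 7.88 with values as deposited. Peak counts of BaitA, BaitB and BaitC were 40964, 40232 and 37911 for all deposited peaks (7567, 7925 and 7449 on the bait arm) and 420, 1662 and 1780 at FDR at most 0.01 (112, 402 and 496). For the named peaks 188 of 194 alternatives stayed within the SD over probes. Merging peaks within 1 kb kept every count within 1.5 times.

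The bait arm ratio of BaitA turned to 1.07 with one peak height, 1.60 at FDR at most 0.01 and 3.65 for top bins, and was 0.938 for all peaks and 0.426 with 200 kb left out. For BaitB it was 9.04 with one peak height, 1.53 at FDR at most 0.01, 170 for top bins, computed with a floor of 3 bins where the other arms had none (exact lower limit 136), and 1.02 with 200 kb left out; for BaitC 1.64, 1.31, 5.31 and 0.779, and 0.916 for all peaks. Between chromosomes the reciprocal signal moved to -0.027 (BaitA array at BaitB), 1.59 (BaitB array at BaitA) and 1.11 (BaitC array at BaitB) within 1 kb, and to -0.65 (BaitB array at BaitA) and -0.051 (BaitC array at BaitB) within 20 kb.

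For BaitA and BaitB, BaitA and BaitC, and BaitB and BaitC, r was 0.445, 0.436 and 0.365 with 5 kb bins and 0.678, 0.619 and 0.475 with 50 kb bins. With no zone left out it was 0.486 (BaitA and BaitB) and 0.368 (BaitB and BaitC), on arms and scaffolds without baits 0.627 and 0.498 for these pairs, and by Spearman 0.466 for BaitA and BaitC. Shared peaks, in the order BaitA with BaitB, BaitA with BaitC and BaitC with BaitB, were 3.58%, 2.67% and 2.65% by reciprocal overlap, 18.9%, 15.7% and 16.8% within 1 kb, and 39.7%, 38.5% and 41.1% for all peaks. At FDR at most 0.01 they were 7.14% for BaitA with BaitB and 2.98% for BaitC with BaitB. All stayed above their shifts, by 1.51 to 6.97 times. Genes with peaks in all 3 baits were 3718 for all mapped peaks, which define the set and so allow no comparison with the product of shares, and 22 at FDR at most 0.01, and genes in exactly 2 were 4965 and 509.

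Of the 60 list alternatives, 51 stayed within the SD of random medians. Within 5 kb the excess over random lists moved to 0.073 for ribosomal protein genes (BaitA), 0.076 (BaitC), 0.36 for architectural proteins (BaitA), -0.032 and 0.19 for hemocyte markers (BaitA and BaitB), -0.29 for neuron markers (BaitC), 0.089 for muscle markers (BaitC) and -0.35 for glycolysis (BaitA). With random lists from any arm it was 0.41 for Polycomb targets (BaitB). The alternatives on the FDR limit of a list's share were not run, as lists were measured by ratios. No paired analysis was possible because each bait had 1 array, with no replicates to pair.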

Other observations

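Next to the centromere, the first 1 Mb of 2R averaged 2.02 ± 0.58 (SD over bins) in the BaitA array, 1.40 ± 0.67 in the BaitB array and 0.42 ± 0.36 in the BaitC array, while the arm beyond 5 Mb averaged 0.22, 0.17 and -0.11. On 3L the last 1 Mb averaged 1.81 ± 0.58, 1.14 ± 0.66 and 0.48 ± 0.32, and on 2L 1.80 ± 0.85, 1.30 ± 0.70 and 0.30 ± 0.39. On X the last 1 Mb was at 0.25 ± 1.00, 0.17 ± 0.94 and 0.40 ± 0.45. On 3R the first 1 Mb was at 0.02 ± 0.96 in the BaitB array, whose bait is on another chromosome.

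A single ribosomal protein gene, RpS13 on 2L, lies within 200 kb of BaitB and was left out of that list for the BaitB array, where it stood at 6.06. Genes whose span, widened by 5 kb, met a peak of each bait numbered 1183 by position, more than the 672 in the peak-to-feature tables, and 547 ± 29.5 (SD over 1000 shifts) after circular shifts of the BaitB and BaitC peaks. That count was chosen after the data had been seen.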
